A study of Mus musculus with 6 samples.

How the data were processed

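RNA from 6 mouse medulloblastomas, 3 with wild type Crebbp and 3 with Crebbp lost, was hybridised to Affymetrix whole-transcript arrays. Samples were grouped by their titles, which also number the tumours 1 to 3 in each group. The label for age gives postnatal day 5, while the treatment protocol gives tamoxifen at postnatal day 5 and collection at postnatal day 60. Day 5 was assumed to be the day of induction and not the age at collection.

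The authors deposited log2 expression values made with RMA in the oligo package, per the submitters' processing notes, and versions are not given in the sources used here. RMA corrects background, equalises the distributions of arrays and summarises probes per feature. This brings arrays to a common scale and compresses changes of dim features, and any change shared by most genes would be removed. The table held 41345 features, with values from 1.84 to 14.4 per array and array medians from 6.91 to 7.00. There are no read depths or detection calls, so dim features were judged against Xist in wild type arrays and Kdm5d, Eif2s3y and Uty in knockout arrays, whose 12 values had a median of 5.11.

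The platform annotation gave 23521 features 1 gene symbol and 1814 several, and 16010 were unnamed here. Of the features with 1 symbol, 99.2% matched a RefSeq gene identifier in the GRCm38.p6 annotation, which changed 0 symbols. That annotation was used for names, chromosomes and gene order only, since the array's build is not stated, and no coordinates are given. For the 1082 genes with several features, the feature with the highest mean over all arrays was used. This left 22180 genes, with no filter on level.

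The values were tested as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All changes are knockout minus wild type on the log2 scale. Crebbp and Ep300 were also tested with an exact permutation test over the 6 arrays. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with fry. A list needed 5 measured members. The lists, chosen before the data were examined, were SHH pathway components and targets, granule neuron progenitor, differentiating granule neuron, granule cell migration, synaptic, DNA replication and mitosis, acetyltransferases and partners, CREB and activity-regulated, p53 target, hypoxia, cholesterol synthesis, Notch, WNT, interferon and MHC presentation genes, and markers of astrocytes and Bergmann glia, oligodendrocytes, microglia and macrophages, endothelium and pericytes, fibroblasts and meninges, Purkinje cells and inhibitory neurons, choroid plexus and ependyma, lymphocytes and blood cells. Sex-linked genes were a check only.

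The rule for named genes was also set before the data were examined. It took Crebbp and Ep300, up to 15 genes with the largest rise and 15 with the largest fall among genes past the threshold whose groups did not overlap, members of each list past the threshold or otherwise the 2 with the smallest p, and Gli1, Ptch1, Mycn, Ccnd1, Atoh1, Mki67 and Bdnf. Predicted genes were only counted. Other list members named in the text were chosen after their values were seen, most because they passed when adjusted over their list alone.

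The fit was tested on simulated data with the real genes' means and residual spread, with 3 arrays per group, 200 of 22180 genes changed and 5 draws. It recovered 24% of genes changed by 0.5 on the log2 scale, 74.4% of those changed by 1 and 95.2% of those changed by 2, and 3.56% of its calls were false. The simulated genes varied independently of each other, so these shares need not hold for real arrays, in which genes vary together. Alternatives covered array scaling, filters on dim genes, the variance model, array weights, the treatment of several features per gene, a replicate block, other thresholds and leaving out each array. Leaving out X and Y genes was added after the data were seen. Sex could not be a covariate because each genotype held 1 sex.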

Results

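Gene expression was measured in 6 mouse medulloblastomas, tumours of the cerebellum, with Affymetrix whole-transcript microarrays. The tumours were driven by SmoM2, an active form of the Sonic hedgehog (SHH) transducer Smoothened, which a tamoxifen-dependent Cre recombinase under Math1 (Atoh1) control switches on in granule neuron progenitors. All animals received 1 mg tamoxifen at postnatal day 5, and tumours were collected at postnatal day 60. In 3 tumours Crebbp, which encodes a histone acetyltransferase, was wild type, and in 3 it was lost with the same recombinase. One array was available per tumour, with 22180 genes tested, and the number of arrays limits the precision. The labels do not state that the tumours of a group came from separate animals or litters, so p-values measure only the spread between these samples.

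The design asks how gene expression differs between SmoM2 tumours with and without Crebbp. The targeted gene was examined first. Crebbp (feature 17327681, chromosome 16) had a log2 level of 11.76 ± 0.05 (SD, n = 3) in wild type tumours and 11.26 ± 0.07 (SD, n = 3) in knockout tumours. All 3 knockout values lay below all 3 wild type values, with a log2 change of -0.50 (SE 0.09), a wild type level 1.41 times that of the knockout. The gene did not pass the threshold over all genes (limma adjusted p = 0.0948), although it passed without the dimmest 50% of genes (adjusted p = 0.0486). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The deleted exons are not given in the labels, so the feature may include probes outside the deletion. Ep300, the paralogous acetyltransferase, had log2 levels of 10.21 ± 0.03 and 10.32 ± 0.12 (SD, n = 3 each), with a log2 change of 0.11 (SE 0.09, adjusted p = 0.652).

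**Figure D1:**
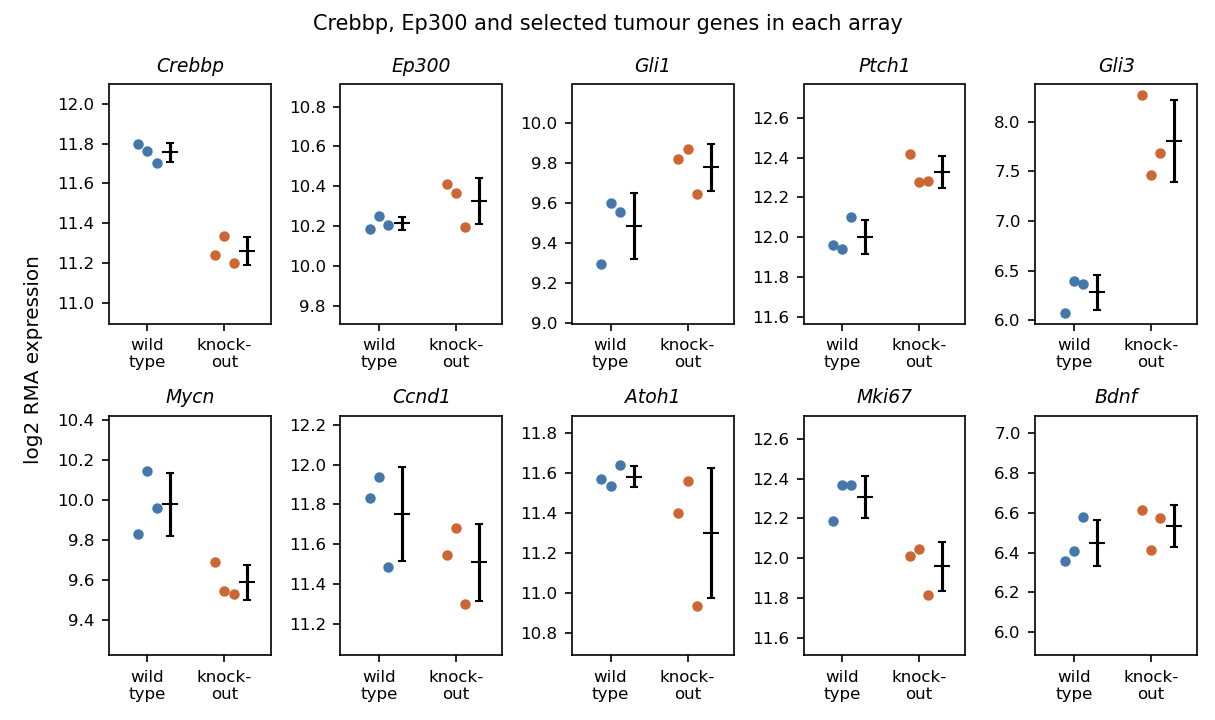
Log2 RMA expression of the targeted gene and of genes of the SHH pathway in each of the 6 arrays, with wild type and knockout tumours side by side and the mean ± SD of each group beside the points. Crebbp lay at 11.76 in wild type and 11.26 in knockout tumours, and Gli3 at 6.28 and 7.80.

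The 2 groups also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of females, had a log2 level of 5.44 ± 0.31 (SD, n = 3) in wild type and 12.34 in knockout tumours. The Y-linked genes Kdm5d, Eif2s3y and Uty had log2 levels of 9.34, 10.11 and 9.64 in wild type tumours and of 4.70, 5.36 and 4.73 in knockout tumours. All 4 genes passed the threshold (limma adjusted p = 1.42e-06, 7.58e-07, 3.15e-06 and 0.000117), with log2 changes of 6.91, -4.65, -4.76 and -4.91. All 3 wild type arrays thus carried the male pattern and all 3 knockout arrays the female pattern, and sex is not given in the labels. Genotype and sex cannot be told apart in these arrays, and this holds for each comparison that follows.

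**Figure D2:**
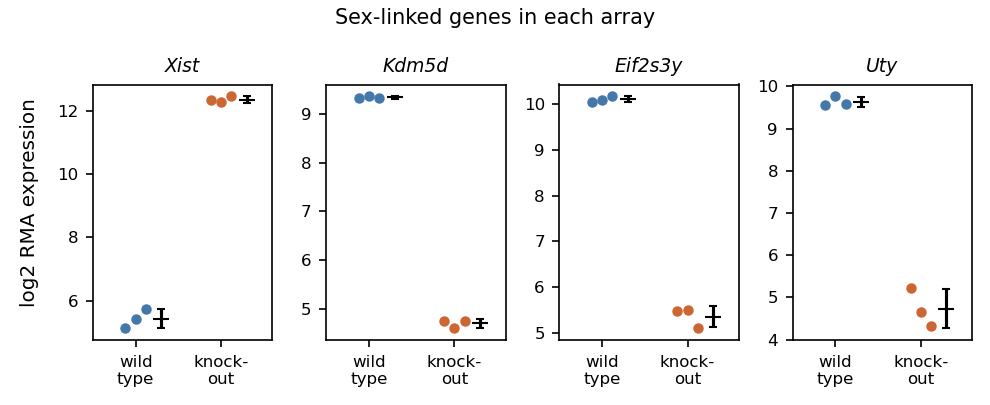
Log2 RMA expression of Xist and of the Y-linked genes Kdm5d, Eif2s3y and Uty in each array, with the mean ± SD of each group beside the points. Xist was high only in the 3 knockout arrays (mean 12.34) and the Y-linked genes only in the 3 wild type arrays.

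Of the genes that rose in knockout tumours, Epha3, an ephrin receptor, had the largest log2 change outside Xist, 2.90 (SE 0.26, limma adjusted p = 0.0121), with mean levels of 7.60 in wild type and 10.51 in knockout tumours. The teneurin Tenm3 rose by 1.92 (SE 0.21), the mitochondrial import component Mtx2 by 1.58 (SE 0.21), the peroxidase family member Gpx8 by 1.57 (SE 0.12) and Gli3, a zinc finger transcription factor of the SHH pathway, by 1.53 (SE 0.20). The growth factor Fgf5, the potassium channel Kcnk9, Ttc23, Cth (an enzyme of cysteine synthesis), the imprinted zinc finger gene Plagl1 and the collagen Col5a2 rose by 1.44, 1.42, 1.36, 1.18, 1.15 and 1.11. Among genes that fell, Serpina3n, a secreted protease inhibitor, fell by 1.91 (SE 0.18), from 10.92 to 9.01, and the chemokine Ccl8 fell by 1.58 (SE 0.12). Shisal2b, Adck5 and Tecta fell too, with log2 changes of -1.82, -1.62 and -1.62.

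The homeobox gene Uncx, the cell adhesion gene Dscaml1, the adhesion receptor Adgrb2, Zbtb42, the Notch regulator Dtx1 and Tspoap1 fell as well, with log2 changes of -1.23, -1.18, -1.10, -1.06, -1.05 and -0.91, and Lpcat2 fell from 8.67 to 7.67. In all, 46 genes passed an adjusted p of 0.05, 28 higher and 18 lower in knockout tumours, and in each of them the values of the groups did not overlap. Over all genes the groups did not overlap in 19.6%, against 10% by chance, and 3050 genes had an unadjusted p under 0.05 where 1109 would be expected. Of the 46 genes, 38 were autosomal and 6 lay on the X or Y chromosome, and 5 were predicted genes that are not named here. Ccl27a, which has near-identical copies, rose from 7.23 to 8.73 and is uncertain for that reason. Myh3 rose by 1.23 from a wild type level of 5.14, and Rpl32l by 1.10 from 3.66. Both levels lay at or below those of sex-linked genes in the sex that lacks them (4.31 to 5.74).

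Which genes passed depended on single tumours. Without knockout replicate 3 only Xist, Kdm5d, Eif2s3y and Uty passed, without wild type replicate 1, wild type replicate 2 and knockout replicate 1 the numbers were 12, 18 and 15, and without wild type replicate 3 and knockout replicate 2 they were 99 and 128.

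**Figure D3:**
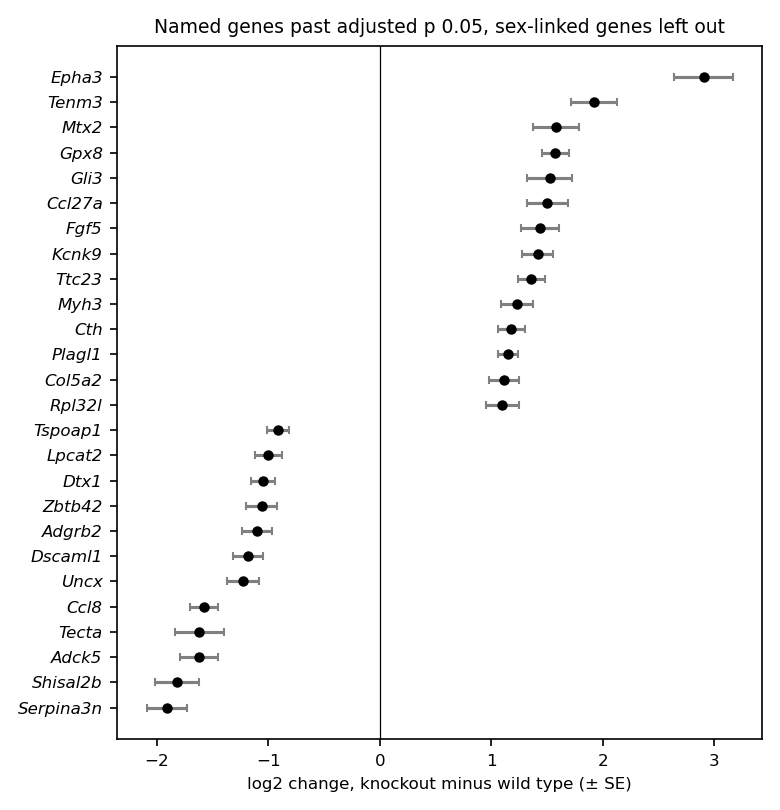
Log2 change (knockout minus wild type, with its SE, n = 3 per group) of the named genes past an adjusted p of 0.05, with sex-linked genes left out. The values run from 2.90 for Epha3 to -1.91 for Serpina3n.

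Genes of the SHH pathway moved in both directions. Gli3 rose, by 1.53 on the log2 scale, and was the only one of the 17 measured members past the threshold over all genes (limma adjusted p = 0.042). Adjusted over the list alone, Gli3, the SHH target and antagonist Hhip (log2 change 1.46) and the receptor Ptch1 (0.33, SE 0.09) rose, and the cyclin Ccnd2 (-0.69), Mycn (-0.39, SE 0.11) and the WNT antagonist Sfrp1 (-0.37) fell. Gli3 and Ptch1 both lie on chromosome 13, where genes past the threshold were more frequent than expected (see Other observations). Gli1, a direct readout of SHH signalling, had a log2 change of 0.30 (SE 0.12, adjusted p over all genes 0.324), and Ccnd1 one of -0.24 (SE 0.15, adjusted p = 0.53). The list as a whole did not shift (median log2 change -0.04, mean 0.09, camera adjusted p = 0.991), while fry's test for change in either direction gave an adjusted p of 0.00254.

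Genes of granule neuron progenitors moved in both directions. Of 17 measured, 13 had negative and 4 positive log2 changes, with a median of -0.32 and a mean of -0.09. The list shifted downward by camera with a preset correlation (adjusted p = 0.000499), but not with one estimated from the data (adjusted p = 0.759 with an estimated correlation). Fry's directional test gave an adjusted p of 0.353 and its test for change in either direction one of 0.00254. Adjusted over the list alone, 9 genes fell and 2 rose, and none passed over all genes. The genes that fell included the transcription factors Insm1 (-0.51, SE 0.10), Zic5 (-0.50, SE 0.10) and Sox11 (-0.57), and those that rose were Mfap4 (2.35) and Eya1. Atoh1, the gene that specifies granule neuron progenitors, had a log2 change of -0.28 (SE 0.16, adjusted p = 0.481). The mean log2 change of the list, -0.09, was -0.02 without wild type replicate 1, -0.05 without knockout replicate 3, -0.14 without knockout replicate 2 and -0.15 without wild type replicate 3, and the call held in each case. The score of the list, the median deviation of its members per array, differed by -0.29 (SE 0.07) between the groups, while those of Purkinje cell and inhibitory neuron markers and of astrocyte and Bergmann glia markers differed by 0.38 (SE 0.17) and 0.30 (SE 0.26). Knockout replicate 2 lay closest to the wild type arrays in the progenitor score (-0.05) and in the Purkinje cell score (-0.09).

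Of 30 genes of DNA replication and mitosis, 28 had negative log2 changes, with a median of -0.17, and the list shifted downward (camera adjusted p = 2.01e-05, adjusted p = 0.838 with an estimated correlation). No member passed over all genes or over the list alone in limma, and 7 had an unadjusted p under 0.05. The proliferation marker Mki67 had a log2 change of -0.35 (SE 0.10), the cell cycle transcription factor E2f1 one of -0.40 (SE 0.11) and Foxm1 one of -0.54 (SE 0.16). Without knockout replicate 3 the mean of the list went from -0.18 to -0.10, and the call held. The score of this list differed by -0.17 (SE 0.09) between the groups, and knockout replicate 2 (0.02) again lay closest to the wild type arrays. The Purkinje cell and glial scores given above were higher on average in knockout tumours, but their groups overlapped (exact permutation p = 0.2 and 0.4). The p53 targets shifted downward as well (20 measured, 15 negative, median -0.17, camera adjusted p = 0.00624, adjusted p = 0.759 with an estimated correlation). Adjusted over the list alone, the cell cycle inhibitor Cdkn1a (-0.80, SE 0.21), the pro-apoptotic gene Bbc3 (-0.61, SE 0.12) and Eda2r fell. The call was lost without the dimmest 50% of genes (adjusted p = 0.0597).

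Markers of microglia and macrophages shifted downward. Of 20 measured, 19 had negative log2 changes, with a median of -0.30 (camera adjusted p = 2.31e-06, adjusted p = 0.759 with an estimated correlation). Adjusted over the list alone 8 genes fell, among them the Fc receptor Fcgr3 (-0.79, SE 0.14), the protease Ctss (-0.57, SE 0.11) and the complement genes C1qa, C1qb and C1qc, and none passed over all genes. Genes of MHC class I and II presentation also shifted downward (14 measured, 12 negative, median -0.30, camera adjusted p = 0.00137, adjusted p = 0.838 with an estimated correlation). Tapbp (-0.40, SE 0.10) fell when adjusted over the list alone, and Psmb8 had a log2 change of -0.48 (SE 0.15). Without wild type replicate 3 this call was lost (mean log2 change -0.14 against -0.30 with all arrays, adjusted p = 0.09).

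Markers of Purkinje cells and inhibitory neurons shifted upward. Of 15 measured, 14 had positive log2 changes, with a median of 0.47 (camera adjusted p = 0.000499, adjusted p = 0.759 with an estimated correlation). Adjusted over the list alone the GABA-synthesising enzyme Gad1 rose (0.47, SE 0.11) and the transcription factor Lhx1 fell (-0.49, SE 0.11). Markers of astrocytes and Bergmann glia shifted upward too (18 measured, 14 positive, median 0.39, camera adjusted p = 0.00624, adjusted p = 0.838 with an estimated correlation). No member passed in limma, 6 had an unadjusted p under 0.05, and Aldoc and Sox2 had log2 changes of 1.47 (SE 0.41) and 0.45 (SE 0.11). The mean log2 change, 0.37, was 0.61 without wild type replicate 3 and 0.23 without wild type replicate 2, where the call was lost (adjusted p = 0.182). All 17 measured genes of cholesterol synthesis had positive log2 changes, with a median of 0.10 (camera adjusted p = 0.00793, adjusted p = 0.838 with an estimated correlation). The X-linked Nsdhl rose when adjusted over the list alone (0.45, SE 0.09), Dhcr7 had a log2 change of 0.31 (SE 0.11), and the call was lost without wild type replicate 3 (adjusted p = 0.512) and with array weights (adjusted p = 0.0658). The mean of the list, 0.14, was 0.21 without wild type replicate 1 and 0.06 without wild type replicate 3.

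In total 8 of 24 lists shifted by camera with a preset correlation, 3 upward and 5 downward. With an estimated correlation 0 lists passed, and 0 had an unadjusted p under 0.05. By fry's directional test 0 passed, and 3 had an unadjusted p under 0.05, while 3 lists passed its test for change in either direction. Among those 3 was the acetyltransferase list, which holds the deleted gene Crebbp and the X-linked Kdm6a.

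**Figure D4:**
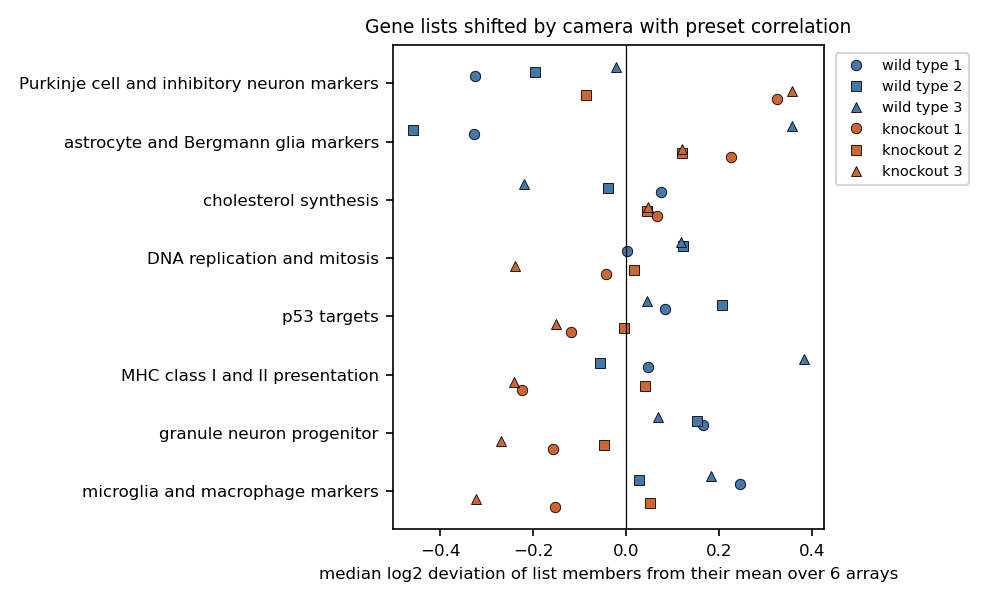
Median log2 deviation of the members of each shifted gene list from their mean over the 6 arrays, with 1 point per array, blue for wild type and orange for knockout. The groups lay apart for granule neuron progenitor genes and p53 targets, while knockout replicate 2 lay within the wild type range for the microglia, mitosis, MHC and Purkinje cell lists, and all 3 knockout arrays did for astrocyte markers (wild type -0.46 to 0.36) and cholesterol synthesis (wild type -0.22 to 0.07).

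The other lists did not shift in the fit of all arrays with a preset correlation. Differentiating granule neuron genes had a median log2 change of -0.07 and a mean of 0.23 (23 measured, camera adjusted p = 0.738), and fry's test for change in either direction gave an adjusted p of 0.193. The proneural factor Neurod1 fell when adjusted over the list alone (-1.14, SE 0.23), while Cbln3, a marker of mature granule neurons, had a log2 change of 2.29 (SE 0.65, adjusted p over all genes 0.21). Acetyltransferases and partners had a median of -0.03 (25 measured, camera adjusted p = 0.314), and fry's test for change in either direction gave an adjusted p of 3.75e-05. Adjusted over that list alone Crebbp fell and Kdm6a, an X-linked demethylase gene expressed from both X chromosomes of females, rose (0.63, SE 0.09, adjusted p over all genes 0.0535). Fry's result for this list may therefore rest on the deleted gene itself and on a gene that differs by sex. It was not repeated without them and says nothing about the other members. CREB and activity-regulated genes had a median of -0.01 (31 measured, adjusted p = 0.738), with Fosl2 at -0.39 and Crem at 0.35. Granule cell migration genes had a median of -0.03 (26 measured, adjusted p = 0.401), with Robo1 at -0.47, Plxnb2 at -0.35 and Bdnf at 0.09 (SE 0.10).

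WNT signalling targets had a median of -0.09 (18 measured, camera adjusted p = 0.423), and adjusted over the list alone Wif1 rose (1.55, SE 0.32) and Nkd1 fell (-0.62, SE 0.16). Notch signalling genes had a median of -0.06 (19 measured, adjusted p = 0.86), with Hes1 at 0.52 and Hey2 at -0.38. Interferon response genes had a median of -0.04 (20 measured, adjusted p = 0.29), and the chemokine Cxcl10 fell when adjusted over the list alone (-1.07, SE 0.18, adjusted p over all genes 0.0816), while Ifit3 lay at -0.36. That list passed without wild type replicate 2 (adjusted p = 0.00888) and without knockout replicate 1 (0.0348), with negative means, while without wild type replicate 3 its mean was 0.000644 (0.885). With all arrays it had an adjusted p = 0.865 with an estimated correlation. Hypoxia response genes had a median of 0.00 (18 measured, adjusted p = 0.423), with Ddit4 at -0.56 and Egln1 at -0.31. Synaptic genes had a median of 0.08 (19 measured, adjusted p = 0.169), with Syt1 at 1.02 and Dlg4 at -0.33, and passed with a positive mean without wild type replicate 1 (adjusted p = 0.0208) and without knockout replicate 2 (0.00599). With all arrays the synaptic list had an adjusted p = 0.838 with an estimated correlation.

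Among markers of other cell types, oligodendrocyte lineage genes had a median log2 change of -0.25 (14 measured, camera adjusted p = 0.0984), with Pdgfra at -0.45 and Sox10 at -0.69. This list passed, with a negative mean, without wild type replicate 3 (adjusted p = 0.000315), without knockout replicate 1 (0.0278), with array weights (0.0119), without the dimmest 50% of genes (0.0306) and with a replicate block (0.0392). Its mean was positive without wild type replicate 1 (0.01, adjusted p = 0.648) and without knockout replicate 2 (0.04, adjusted p = 0.752), and with all arrays it had an adjusted p = 0.838 with an estimated correlation. Endothelial and pericyte markers had a median of 0.09 (18 measured, adjusted p = 0.118), and adjusted over the list alone the basement membrane collagen Col4a1 (0.63) and the receptor Tek (0.50) rose. That list passed, with a positive mean, without wild type replicate 3 (adjusted p = 0.0331), without knockout replicate 2 (0.00599) and with array weights (0.0493), and with all arrays it had an adjusted p = 0.838 with an estimated correlation. Fibroblast and meningeal markers had a median of 0.07 (15 measured, adjusted p = 0.76), with the growth factor gene Igf2 (1.39, SE 0.26) higher when adjusted over the list alone and Foxc1 at -0.45. Lymphocyte markers had a median of -0.07 (15 measured, adjusted p = 0.209), with Cd79a at -0.32 and Ptprc at -0.48. Choroid plexus and ependymal markers had a median of -0.04 (11 measured, adjusted p = 0.775), with Tmem212 at 0.33 and Aqp1 at -0.32. Blood cell markers had a median of -0.01 (5 measured, adjusted p = 0.988), with S100a8 at -0.30 and Slc4a1 at 0.24. The levels of Tmem212 (4.80 and 5.13) and S100a8 (5.23 and 4.94) in wild type and knockout tumours, and that of Slc4a1 in wild type tumours (5.73), lay at those of absent sex-linked genes.

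The arrays resembled each other closely over all genes, with Pearson correlations across genes of 0.984 to 0.993 between pairs, a mean of 0.991 within groups and 0.987 between groups. Genes are not independent replicates, and no test was made of this difference. The first principal component held 40.7% of the variance and placed the 3 wild type arrays apart from the 3 knockout arrays. The second held 20% and set wild type replicate 3 apart from the other arrays.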

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

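The test of genes that escape X inactivation and the swap test were chosen after the sex-linked genes had been seen, and the test of unnamed features was set before the data were examined. When all 41345 features were tested alone, 10 features without a single gene symbol passed an adjusted p of 0.05 in limma, of 17824 such features, which lie outside the comparison of named genes. Of these 6 were higher and 4 lower in knockout tumours. The largest changes were 7.29 (SE 0.09, feature 17550478) and 6.65 (SE 0.20, feature 17550444), with -3.72 (SE 0.15, feature 17546834) the largest fall, and these features were chosen after their values were seen. Their genes were not identified here.

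The complete parting of the groups by Xist and Y-linked genes may reflect the sex of the animals. Genes known to escape X inactivation had a median log2 change of 0.397 (score SE 0.0439, positive in 6 of 6 genes), against a median of 0.0289 over all X-linked genes, which is what 2 X chromosomes in the knockout animals would give. A swap of tumours between the groups is argued against, since 0 arrays had a Crebbp value inside the range of the other group. A design with both sexes in each genotype was not analysed here.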

How the results depend on the processing

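Leaving out X and Y genes was chosen after the data were seen, and all other alternatives were planned. The 46 genes past the threshold (28 higher, 18 lower) kept their direction in every fit in which they were tested. This was largely fixed in advance. Their groups did not overlap, so leaving out an array cannot turn a sign, and filters and variance models leave log2 changes as they are. The number of genes past the threshold varied. It was 77 (36 lower) without the dimmest 25% of genes, of which 43 were among the 46, and 35 genes were lower without the dimmest 50%. It was 137 (59 higher, 78 lower) with a trended, robust variance model. With array weights 28 were lower. It was 22 (12 higher, 10 lower) over all features, 4 (1 higher, 3 lower) without variance moderation and 131 (68 higher, 63 lower) at an adjusted p under 0.1. Without X and Y genes 36 passed, all among the 46. Leaving out 1 array gave 4 to 128 genes (1 to 91 higher, 3 to 50 lower), and Xist, Kdm5d, Eif2s3y and Uty alone passed in all 6 such fits. The cause was not tested, apart from the fewer samples and genes tested.

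No clear pairing of the tumours by replicate number was seen. Deviations of same-numbered arrays correlated at -0.0286, 0.0523 and 0.0996, none of them above 0.1. With 3 arrays per group and no litter or day in the labels, pairing is not excluded. Wild type replicates 2 and 3 correlated best with the knockout replicate of their own number, and wild type replicate 1 with knockout replicate 2. With a replicate block 12 genes passed (7 higher, 5 lower), all among the 46. Crebbp passed in limma without the dimmest 50% of genes (adjusted p = 0.0486) and with the trended model (0.0234). Its log2 change of -0.50 stayed the same there by construction. Without 1 array its change ran from -0.54 to -0.47. The within-group minus between-group correlation rose from 0.00424 to 0.0188 without the dimmest 50%.

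Of the gene lists, 0 shifted with an estimated correlation (0 higher, 0 lower) and 0 by fry (0 higher, 0 lower), against 8 by camera, for which leaving out 1 array gave 2 to 5 higher. Calls gained by the oligodendrocyte, interferon, synaptic and endothelial lists, and calls lost, stand beside those lists. Means of shifted lists moved by over 1.5 times without 1 array for granule neuron progenitor (-0.15 to -0.0189), DNA replication (-0.227 to -0.101), MHC (-0.421 to -0.136), astrocyte (0.227 to 0.605) and cholesterol genes (0.0575 to 0.208), with no change of sign. Mean log2 changes that turned sign belonged to lists that had not shifted. Without the dimmest 50% SHH genes gave -0.00667 and Notch genes 0.0468. With array weights Notch gave 0.00875 and blood markers -0.00696. With median-centred arrays WNT, fibroblast and blood lists gave -0.028, -0.0171 and -0.0253, and with renewed quantile normalization -0.0118, -0.0039 and -0.00556. With feature means WNT and fibroblast lists gave -0.0151 and -0.0199, and without X and Y genes the fibroblast list gave -0.0161. Without 1 array the ranges were -0.097 to 0.0394 (migration), -0.0562 to 0.00114 (acetyltransferases), -0.0301 to 0.00493 (CREB), -0.0657 to 0.0565 (Notch), -0.0668 to 0.0449 (WNT), -0.189 to 0.000644 (interferon), -0.236 to 0.0414 (oligodendrocyte), -0.13 to 0.198 (fibroblast) and -0.0664 to 0.102 (blood). Sex as a covariate was not run because each genotype held 1 sex, and set tests were not run with the trended model or without moderation. Signal near the level of absent genes limits Myh3, Rpl32l, Tmem212, S100a8 and Slc4a1.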

Other observations

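The imprinted list, the gene families, the chromosome 13 tests and all tests of mature cell markers were chosen after results had been seen, while the chromosome 16 test, the test of sex within genotypes and the splits of the arrays were planned. Among 27 measured imprinted genes, which are expressed from 1 parental copy, Plagl1, Zdbf2 (log2 change 1.87), Grb10 (2.29) and Igf2 (1.39) rose and Gatm and Dlk1 fell when adjusted over the list alone. The list as a whole did not shift by camera (14 positive, 13 negative, median 0.03, p = 0.0787, and p = 0.12 with an estimated correlation). Its score, the median deviation per array, was higher by 0.09 (SE 0.02) in knockout tumours, with all 3 knockout values (0.0268 to 0.0492) above all 3 wild type values (-0.0864 to -0.00897) and an exact p of 0.1, but the list was drawn up after Plagl1, Igf2 and Zdbf2 had been seen and is not independent evidence. Families of genes were also formed by symbol stem alone, whatever the function of the members. Of 252 such families, those with the stems Cdkn (9 of 10 negative, median -0.32) and Sema (18 of 20 negative, median -0.16) shifted downward (camera adjusted p = 0.0387 for both). Neither call held with an estimated correlation (adjusted p = 0.987 for both).

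The autosomal genes past the threshold numbered 38, and whether they follow Crebbp or sex cannot be told apart, because only 1 sex was found within each genotype. Alleles carried along with the Crebbp locus are argued against as the main source, since 1 such gene, Epha3, lay on chromosome 16 where 1.27 would be expected (odds ratio 0.784) and 0 of 242 genes tested within 20 Mb of Crebbp passed. Chromosome 13 held 8 of the 38, among them Gli3, Gpx8 and Shisal2b, where 1.55 would be expected (Fisher's exact test adjusted p = 0.0023 over the autosomes), and 6 genes with an adjusted p under 0.1 fell in 1 window of 100 neighbouring genes (permutation p = 0.0229). All 6 were higher in knockout tumours and lay at positions 505 to 570 of the 858 chromosome 13 genes in order. Gli3, Shisal2b and Gpx8 lay at 59, 772 and 815, so a segment confined to the window would not cover them. Slc35d2, Zfp493 and a predicted gene counted in both results, so the window is not separate evidence. It also held other zinc finger genes, such as Zfp808 and Zfp458, which may vary together, while both tests take genes as independent. A chromosome 13 segment that differs between the groups may contribute. The next genes, with adjusted p from 0.05 to under 0.1, had an odds ratio of 1.59 (Fisher's exact test p = 0.259), which leaves it open.

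In markers of mature cerebellar cells, median log2 changes were 1.04 for granule neurons, 0.844 for Purkinje cells, 0.435 for astrocytes and Bergmann glia and -0.055 for oligodendrocytes, but 0 members passed over all genes in limma, and 5 granule neuron and 4 Purkinje genes rose over their lists alone (6 of 8, 4 of 6, 4 of 11 and 1 of 9 had an unadjusted p under 0.05). Exact p-values of the scores were 0.2, 0.2, 0.4 and 0.6, and camera p-values with an estimated correlation 0.17, 0.0633, 0.296 and 0.988. Knockout replicate 2 lay within the wild type range for granule neurons (-0.301 in -0.922 to -0.162) and Purkinje cells (-0.25 in -0.556 to -0.142), as did all 3 knockout arrays for glia (0.184 to 0.255 in -0.616 to 0.357). The granule neuron list held every member of the planned differentiating list that rose with an unadjusted p under 0.05 in limma. It was chosen after those values had been seen and is not independent evidence. The planned differentiating list had a median of -0.07 (23 measured, camera adjusted p = 0.738). The Purkinje list was likewise taken from a planned list, that of Purkinje cells and inhibitory neurons, after values had been seen. It left out Lhx1, the only planned member with a negative log2 change (-0.49), and is not independent evidence either. Microglia markers (19 of 20 negative, score -0.294, SE 0.126) ran against a lower share of tumour cells with every other type raised alike. The Purkinje minus the oligodendrocyte score (0.881, SE 0.352, exact p = 0.1) went the same way. That test was added after a first one on the lowest of the 4 medians (-0.055) had left normal cerebellum open. Both of its lists were cut from planned lists after values had been seen, so by itself it argues against no explanation. The other measured genes of the planned oligodendrocyte lineage list, Pdgfra, Sox10, Cspg4, Olig1 and Olig2, were lower too. Of these 5 of 5 were negative (median -0.429, 4 fell over the list alone, score -0.426, SE 0.173, exact p = 0.2, camera p = 0.0767 with an estimated correlation). The planned list (14 measured, median -0.25, camera adjusted p = 0.0984) was split in this way after values had been seen. The split is thus not independent evidence that precursors and mature cells differed. The 5 genes bear on this share only if they come from cells other than tumour cells, which was not tested. Pdgfra, 1 of them, had a log2 level of 12.14 in wild type tumours and lay at the 99th percentile of genes by mean level. None of these scores reached 2.78 standard errors, the limit for 4 degrees of freedom. More normal cerebellum or cortex, a lower share of tumour cells and differentiation of tumour cells alone could thus each contribute and cannot be told apart. The same holds for the lower score of the mitosis list (-0.169, SE 0.0867). The lower score of the granule neuron progenitor list (-0.287, SE 0.0707) did pass that limit, with the groups apart. A fall of that score could come with each of these explanations, so it does not tell them apart either. A limit of 2 standard errors was used at first and replaced because it is too low for 3 against 3 arrays. It would have argued against the equal rise and, by the Purkinje score, against differentiation alone. The lists behind both readings were chosen after values had been seen.

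The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 46 genes, as did 1 of the 10 with itself included, and the highest other gave 0 in limma, with up to 1815 genes at an unadjusted p under 0.05 against 3050. Adjusted among autosomal genes alone the real split gave 34 and the highest other 0, so that 1 split reached the real value. For gene lists the real split gave 8 and the highest other 10, and 6 of the 10 splits gave at least 8.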
